A study of Mus musculus with 12 samples.

How the data were processed

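Total RNA of mouse colonic epithelium was sequenced in 12 libraries, 3 of crypts and 3 each of confluent monolayers at day 3, day 4 and day 5. Samples were grouped by the labels alone, and the replicate numbers in the labels serve here as names. Per the labels' protocols, RNA was isolated with the RNAqueous Micro kit. The values used are the counts deposited by the authors, 1 file per library, which hold whole numbers of reads per gene with no normalization. Per the submitters' processing notes, CASAVA 1.9, TopHat2 and HTSeq were used, and the genome builds mm9 and mm10 are both named without a role. No coordinates are therefore printed. The gene annotation, the strand setting of the counting and the versions of TopHat2 and HTSeq are not given in the sources used here. Without strand, reads of a gene and of an antisense or overlapping partner cannot be told apart, so genes with such partners are uncertain.

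Each deposited count file held 23420 gene symbols and 5 summary lines of the counter, which name no gene and stayed out of library sizes and tests. The summary line for reads in no gene held 38.7 to 49% of all reads counted, 47.3 ± 1.7% in crypts (SD, n = 3) and 40.2 ± 1.25% in monolayers (n = 9). Reads without a unique alignment held 14.2 to 19.2%, and reads overlapping several genes 0.154 to 0.207%. Reads in genes held 31.7 to 43.5%. Since reads without a unique alignment were left out before deposit, counts of genes with near-identical copies are uncertain: ribosomal protein genes and other genes with processed pseudogenes, and the Cyp2c, Cyp2d, Ces, H2-Q, Reg3, Saa, Sprr and histone families.

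Depth, as the total of gene counts, was 4518314, 7130784 and 9939045 in crypts replicates 1 to 3, 10237459, 14290393 and 13531646 at day 3, 12227445, 10911508 and 8289826 at day 4, and 5456913, 11716792 and 5760580 at day 5. A floor of 3 counts corresponds to between 0.215 and 0.605 CPM, depending on the library. No pair of libraries of a group agreed within sampling noise in a chi-square comparison of their counts, so all 12 were used.

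Counts were tested in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups given and a minimum count of 10, which left 12863 genes, libraries were scaled by TMM factors (0.91 to 1.12), and the quasi-likelihood test (glmQLFit and glmQLFTest) was applied in 1 fit of all 12 libraries with the group as its term. The contrasts were the mean of the 3 monolayer days against crypts, each day against crypts, and each pair of days. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Each log2 fold change is given with its standard error, taken from the fold change and the F statistic. Levels are TMM-scaled CPM, given as mean ± SD. Where a group had no count of a gene, the fold is a lower bound against a floor of 3 counts pooled over the group. Where it had 1 to 3 counts, or a monolayer day averaged with the others had at most 3, the ratio of pooled CPM is given with an exact 95% interval. Such intervals and floors cover counting error only.

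A total of 37 gene lists of cell types, pathways and complexes, with 1038 distinct genes, was fixed before the data were examined, as were the groups, the tests, the alternatives and the rule for named genes. The 35 lists with at least 5 tested members were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) at its preset correlation between genes of 0.01, with adjustment over the lists, and again with the correlation estimated from the data. Calls of list members were also adjusted over the list alone. Named genes were the 10 largest changes each way between monolayers and crypts, with a mean of at least 8 CPM, a call at every day and no overlap between libraries. For pairs of days they were the 5 largest each way, with the same mean and no overlap. The mean was taken over all 12 libraries, so a gene could pass with few counts on the days compared. Up to 4 called members of each list with a mean of at least 1 CPM were added, as were 31 genes named whatever their value. Unnamed gene models and small RNAs were passed over. Some genes this rule selects are not reported here.

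The main edgeR test and camera at its preset correlation were tried on simulated data with the means, dispersions and library sizes of these samples. In these simulated data 12623 of 12863 genes were unchanged. In the real data 63.5% of the genes tested were called between monolayers and crypts. The simulation therefore does not show how scaling or false calls behave when most genes change. The alternatives and the further tests were not run on simulated data. For monolayers against crypts, where 12640 genes passed the filter, 41.8% of genes changed 1.5-fold, 71.6% of those changed 2-fold and 90.9% of those changed 4-fold were recovered, with 14 calls among the unchanged genes. For day 4 against day 3 (12614 genes) the shares were 34.3, 64.2 and 81.8%, with 4 such calls. For day 5 against day 4 (12644 genes) they were 31.3, 61.2 and 78.8%, with 10. For day 5 against day 3 (12635 genes) they were 29.9, 58.2 and 86.4%, with 13. A simulated list of 40 genes changed 1.5-fold was called in each of these 4 comparisons, and 0 of 34 unchanged lists were. Simulated genes varied independently of each other, unlike real lists (estimated correlation 0.665 for interferon response genes). False calls of lists whose genes vary together were therefore not tested.

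The alternatives were DESeq2 size factors or library totals in place of TMM, no filter beyond 1 count in any library, at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, the replicate number as a block, a minimum change of 2-fold, glmTreat against 1.5-fold, camera with the estimated correlation, fry in place of camera, and each of the 12 libraries left out in turn. A count with crypts replicate 2 and day 5 replicate 1 left out together was added after the data were seen. With a library left out the filter was applied again, so the genes tested and the tested members of a list could change. Groups of 3 are too small for an outlier test, so no library was removed.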

Results

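Confluent monolayers of mouse colonic epithelium at day 3, day 4 and day 5 were compared with crypts, in 12 libraries with 3 per group. Per the labels, cells from crypts of a wild-type mouse were expanded on collagen and replated on scaffolds with graded cross-linking. The labels give a transepithelial resistance of 526 ± 56 ohm cm2 at day 3, 623 ± 15 at day 4 and 407 ± 53 at day 5, without naming the type of error. Levels are mean CPM (counts scaled to library size) ± SD, with n = 9 for monolayers, n = 3 for crypts and n = 3 for each day unless given otherwise. Changes are log2 fold changes ± SE with the edgeR adjusted p. Where a group had no count of a gene, the fold is at least the value against a floor of 3 counts. Where it had 1 to 3 counts, a ratio with its exact 95% interval is given, and both cover counting error only. Whether the 3 libraries of a group come from separate mice or cultures is not given in the sources used here, so the p-values measure only the spread between these samples. The fit takes 1 estimate of spread per gene from all 12 libraries, so tests between days also carry the spread of the crypts.

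Crypts and monolayers separated along the first principal component of log2 CPM, which held 71.6% of the variance. Crypts lay between -155 and -150.7 on it and monolayers between 48.7 and 55.6. The second component (10.5%) separated day 5 replicate 1 at 93.2 from day 5 replicates 2 and 3 at 26.3 and 19.8. Crypt libraries correlated with each other at r of 0.949 to 0.957 and with monolayers at 0.715 to 0.736. Day 3 libraries correlated with each other at 0.983 to 0.99, day 4 at 0.977 to 0.979 and day 5 at 0.946 to 0.981. Day 5 replicate 1 had the fewest genes with a count, 12293 against up to 15250. The nuclear RNA Malat1 took 2.21 ± 0.168% of gene counts in crypts, 5.81 ± 0.165% at day 3, 7.72 ± 0.325% at day 4 and 11 ± 1.51% at day 5. Reads in no gene were 47.3 ± 1.7% of reads counted in crypts and 40.2 ± 1.25% in monolayers.

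**Figure D1:**
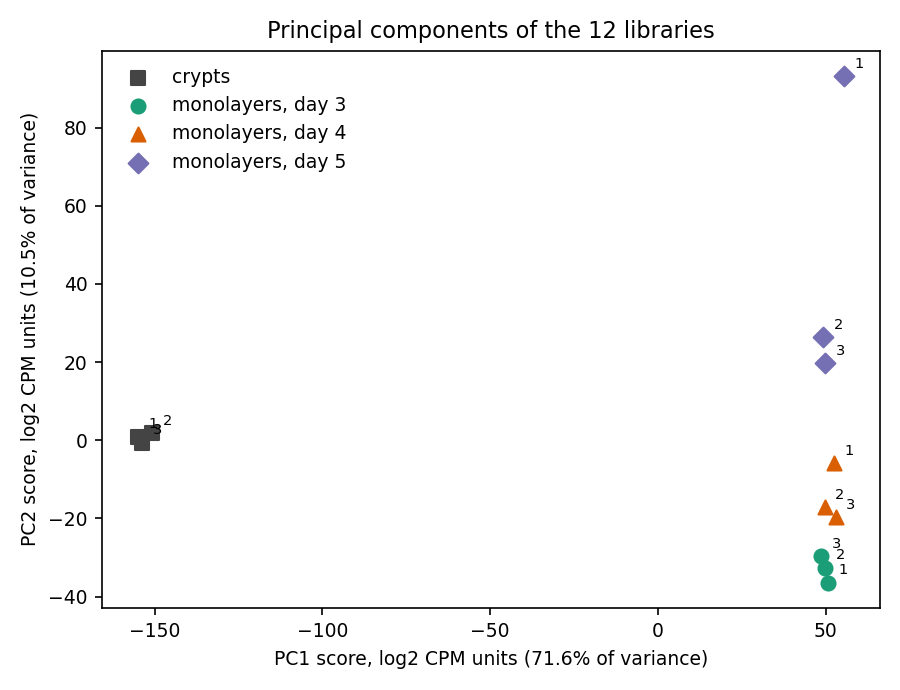
Principal components of log2 CPM of the 12 libraries, coloured by group, with the replicate number beside each point. The first component holds 71.6% and the second 10.5% of the variance.

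Genes of mature colonic cells were lower in monolayers than in crypts, and genes of epithelial repair were higher. Muc2, the secreted mucin of goblet cells, stood at 14.2 ± 15.4 CPM in monolayers against 24500 ± 1400 in crypts (-10.91 ± 0.39, edgeR adjusted p = 2.62e-14). Msln, a surface protein of fetal and injured epithelium, reached 676 ± 70.8 against 0.875 ± 0.628 CPM (9.84 ± 0.21, edgeR adjusted p = 3.76e-17). Ly6a (Sca-1), a marker of regenerating colon, was at 1500 ± 233 against 112 ± 74.4 CPM (3.73 ± 0.28, edgeR adjusted p = 9.45e-10). The adhesion gene Cdh1 was not called (1480 ± 127 against 1460 ± 130 CPM, 0.02 ± 0.06, edgeR adjusted p = 0.823), although it was called lower with library totals in place of TMM (-0.16, edgeR adjusted p = 0.0274). Leaving out 1 library moved Muc2 to -11.5 (day 5 replicate 1), Msln to 9.14 (crypts replicate 3) and Ly6a to 4.44 (crypts replicate 2).

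Several of the largest increases were in genes with no count in crypts. They included Ctgf, a matrix-associated YAP target (697 ± 239 CPM in monolayers, at least 5830-fold), Krt4, a keratin of stratified epithelium (147 ± 117, at least 1320-fold), and Il5ra, a cytokine receptor chain (90.6 ± 16.3, at least 721-fold). The small heat shock protein gene Cryab (86.3 ± 19.3, at least 667-fold), the protease inhibitor gene Serpinb11 (68.6 ± 25.1, at least 497-fold) and Samd4, a regulator of mRNA translation (40.9 ± 5.71, at least 329-fold), followed. The autophagy gene Atg9b (194 ± 31 CPM) was higher by a ratio of 4480 (804 to 177000), and the prostaglandin synthase gene Ptgs2 (185 ± 60.3 CPM) by 2320 (643 to 19200). The crypt counts of both, 1 and 2, were all in replicate 3.

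Of the 10 largest decreases, 4 genes had no count in monolayers: Retnlb, a bactericidal goblet cell product (455 ± 402 CPM in crypts, at least 10900-fold lower), Nov, a matricellular protein gene (185 ± 79.6, at least 6100-fold), Rgs17, a brake on G protein signalling (52.4 ± 20.6, at least 1650-fold), and the lipase cofactor gene Clps (48.6 ± 35.6, at least 1220-fold). The antimicrobial lectin gene Reg3g was lower by a ratio of 10600 (1890 to 417000) and the tyrosine catabolism gene Hpd by 5920 (1060 to 234000). Mptx1, a pentraxin gene of the gut, was at 0.219 ± 0.527 against 3770 ± 3190 CPM, lower by a ratio of 25000 (14300 to 48400). The surface carbonic anhydrase gene Car4 was at 0.119 ± 0.265 against 458 ± 44.6 CPM, lower by a ratio of 6930 (3180 to 18900, edgeR adjusted p = 2.05e-16), with no count at day 3 or day 4. Reg3b, a second lectin gene, was lower by 3620 (1970 to 7560) and Pck1, of gluconeogenesis, by 2650 (1220 to 7230). Several of these sizes rest on 1 crypt library: replicate 2 held 306 of the Reg3g CPM against 49.7 and 18.3 in replicates 1 and 3, and 1040 of the Reg3b CPM against 184 and 61.8. Replicate 1 held 918 CPM of Retnlb against 255 and 192, 89.7 of Clps against 29 and 27.2, and 7090 of Mptx1 against 737 and 3470. Leaving out day 5 replicate 1 moved Mptx1 from -14.86 to -16.5, Reg3b from -12.78 to -14.49 and Pck1 from -11.86 to -12.62.

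Goblet cell genes were the most reduced lineage, with 30 of 33 lower, 3 higher and a median of -6.85 (camera adjusted p = 5.98e-12). Their summed level was 888 ± 47.1 against 39700 ± 6250 CPM. Fcgbp, a mucus-binding protein gene (-9.15 ± 0.23), the trefoil factor gene Tff3 (-6.74 ± 0.19), the kallikrein gene Klk1 (by a ratio of 2900, 2110 to 4130) and Atoh1, the master regulator of secretory fate (908, 440 to 2260), were all lower. Of 19 enteroendocrine genes 16 were lower and 1 higher (median -4.74, camera adjusted p = 4.42e-06, adjusted p = 0.0597 with an estimated correlation). Chga, a granule protein gene of endocrine cells, was at 4.09 ± 1.06 against 135 ± 77.2 CPM (-5.05 ± 0.23, or -4.47 without crypts replicate 3). Tuft cell genes had 16 of 21 lower and 2 higher (median -4.2, camera adjusted p = 9.63e-05), among them the tuft marker Dclk1, lower by a ratio of 87 (53.7 to 151). The Dclk1 change of -6.84 was -7.63 without day 3 replicate 2 and -8.18 without day 5 replicate 2. Small intestine and Paneth cell genes had 11 of 14 lower and 1 higher (median -3.95, camera adjusted p = 0.000368, adjusted p = 0.112 with an estimated correlation). Sis, the sucrase-isomaltase gene, had no count in monolayers (at least 496-fold lower).

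Absorptive colonocyte genes had 31 of 38 lower and 5 higher (median -1.63, camera adjusted p = 6.37e-08, adjusted p = 0.0854 with an estimated correlation). The guanylin gene Guca2a fell to 2.05 ± 1.44 from 1220 ± 155 CPM (-9.3 ± 0.17), the chloride exchanger gene Slc26a3 to 28.7 ± 16.3 from 434 ± 38.7 (-4.08 ± 0.13) and Krt20, a keratin of surface cells, to 93 ± 63.6 from 1270 ± 342 (-4.05 ± 0.14). Of 32 ion and water transport genes 27 were lower and 1 higher (median -1.31, camera adjusted p = 1.91e-08). They included the water channel gene Aqp8 (-8.73 ± 0.18, edgeR adjusted p = 1.63e-17) and the butyrate transporter gene Slc5a8 (-7.04 ± 0.13), while the carbonic anhydrase gene Car1 was lower at -0.9 ± 0.14 (edgeR adjusted p = 1.77e-05). Colon regional identity genes, with 10 of 18 lower and 4 higher, were not called as a list (median -1.33, camera adjusted p = 0.0716). The intestinal homeobox genes Cdx1 and Cdx2 were lower at -3.94 ± 0.23 and -0.51 ± 0.12 (edgeR adjusted p = 0.00131).

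Proliferation genes were lower, with 39 of 44 cell cycle genes lower and 0 higher (median -1.77, camera adjusted p = 2.15e-08, adjusted p = 0.0982 with an estimated correlation). Mki67, expressed in cycling cells, was at 258 ± 180 against 961 ± 111 CPM (-2.5 ± 0.12, edgeR adjusted p = 1.43e-12), and the replication licensing gene Mcm6 was lower at -2.86 ± 0.22. Histone genes had 15 of 18 lower (median -1.52, camera adjusted p = 0.00038, adjusted p = 0.19 with an estimated correlation), among them the linker histone gene Hist1h1a (-3.51 ± 0.2). Stem cell genes split into 9 higher and 10 lower of 24 (median -0.23, camera adjusted p = 0.764). Lgr5, the receptor marking crypt base stem cells, was at 4.54 ± 2.43 against 12.6 ± 8.09 CPM (-1.7 ± 0.33, edgeR adjusted p = 0.000191). Crypts replicate 2 held 21.8 CPM of Lgr5 against 6.41 and 9.74 in replicates 1 and 3, and the change was -1.06 without it. Of 14 Wnt genes 7 were higher and 4 lower (median 0.57, camera adjusted p = 0.226). The feedback gene Axin2 was at 155 ± 31.5 against 64.7 ± 11.1 CPM (1.23 ± 0.13, edgeR adjusted p = 1.15e-07) and the growth regulator Myc at 170 ± 71.6 against 25.3 ± 4 (2.65 ± 0.13). Notch genes had 6 higher and 6 lower of 14 (median -0.06, camera adjusted p = 0.958), with the ligand genes Dll4 and Dll1 lower at -4.44 ± 0.45 and -4.04 ± 0.36. BMP and TGF-beta genes had 10 higher and 11 lower of 25 (median -0.14, camera adjusted p = 0.958), with the activin gene Inhba at least 72-fold higher.

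Junction genes moved both ways, with 21 of 38 higher and 8 lower (median 0.38, camera adjusted p = 0.00579, adjusted p = 0.288 with an estimated correlation). Cldn4, a sealing claudin gene, was at 270 ± 42.4 against 13.7 ± 4.81 CPM (4.34 ± 0.17, edgeR adjusted p = 1.22e-13), and the scaffold gene Tjp1 at 794 ± 48.3 against 252 ± 18.7 (1.66 ± 0.08, edgeR adjusted p = 9.42e-13). The pore-forming claudin gene Cldn2 was lower by a ratio of 320 (225 to 472), Cldn15, also pore-forming, at -5 ± 0.2, and Cldn8, a claudin gene of distal colon, at -4.52 ± 0.19. Ocln and Cldn3 were not called (0.17 ± 0.08 and -0.08 ± 0.07, edgeR adjusted p = 0.0709 and 0.368), and the microvillus gene Vil1 was lower at -0.45 ± 0.08. The adhesion gene Epcam was called lower (-0.26 ± 0.08, edgeR adjusted p = 0.00711) but not without crypts replicate 2 (-0.16, 0.0951).

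Repair and fetal-like epithelium genes were higher for 39 of 41, with 0 lower (median 3.45, camera adjusted p = 1.52e-18), and summed to 22000 ± 3470 against 4630 ± 266 CPM. YAP target genes had 17 of 21 higher and 2 lower (median 2.73, camera adjusted p = 1.21e-06), among them F3, which encodes tissue factor (1070 ± 93.9 against 20.6 ± 5.12 CPM, 5.73 ± 0.13). Of 31 basement membrane and integrin genes 24 were higher and 2 lower (median 1.71, camera adjusted p = 1.91e-08, adjusted p = 0.0597 with an estimated correlation). The collagen IV gene Col4a2 was at 421 ± 56.5 against 1.59 ± 0.883 CPM (8.01 ± 0.18) and the laminin gene Lama5 at 599 ± 56 against 9.94 ± 0.586 (5.91 ± 0.12).

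Glycolysis and hypoxia genes were higher for 30 of 33, with 2 lower (median 2.11, camera adjusted p = 7.55e-13), and summed to 15600 ± 1200 against 3300 ± 188 CPM. The lactate exporter gene Slc16a3 (6.12 ± 0.16), the hypoxia-induced mitophagy gene Bnip3 (5.77 ± 0.19) and the glycolytic activator gene Pfkfb3 (5.64 ± 0.15) were higher. Oxidative phosphorylation genes had 39 of 41 lower and 0 higher (median -0.88, camera adjusted p = 1.83e-11, adjusted p = 0.0597 with an estimated correlation), such as the cytochrome oxidase gene Cox5b (53.1 ± 4.38 against 182 ± 15.9 CPM, -1.78 ± 0.08). Fatty acid oxidation and ketogenesis genes had 28 of 35 lower and 2 higher (median -1.07, camera adjusted p = 6.98e-06, adjusted p = 0.0727 with an estimated correlation), including the lipid receptor gene Ppara (-5.31 ± 0.34). Cholesterol synthesis genes were higher for 22 of 26 and lower for 2 (median 1.45, camera adjusted p = 3.19e-08, adjusted p = 0.0813 with an estimated correlation), with Lss, which closes the sterol ring, higher by 2.67 ± 0.14. Xenobiotic metabolism genes had 29 of 47 lower and 14 higher (median -1.44, camera adjusted p = 0.0145, adjusted p = 0.219 with an estimated correlation). The sulfotransferase gene Sult1a1 was lower at -9.13 ± 0.16.

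The unfolded protein response (10 higher and 9 lower of 28, median -0.05, camera adjusted p = 0.648) was not called as a list, although its transcription factor gene Ddit3 was higher by 2.45 ± 0.2. Circadian clock genes (10 higher and 5 lower of 18, median 0.67, camera adjusted p = 0.117) included the repressor gene Bhlhe40, at 530 ± 38.6 against 113 ± 4.84 CPM (2.23 ± 0.08). Glucocorticoid and mineralocorticoid targets (4 higher and 10 lower of 15, median -1.69, camera adjusted p = 0.063) included the cortisol-inactivating enzyme gene Hsd11b2, lower by a ratio of 515 (366 to 748), and the receptor cochaperone gene Fkbp5 at -4.2 ± 0.21. Immediate early and heat shock genes (15 higher and 8 lower of 29, median 0.35, camera adjusted p = 0.0692) included the stress gene Ier3 at 5.78 ± 0.18, and were called without day 3 replicate 1 (0.0474) or day 5 replicate 1 (0.0416). Ribosomal protein genes had 14 of 39 higher and 2 lower over all days (median 0.23, camera adjusted p = 0.0521). Leaving out any 1 library other than crypts replicate 2 made this list called, at 0.0396 and 0.0314 without crypts replicates 1 and 3, 0.0378, 0.0467 and 0.0191 without the day 3 replicates in order, 0.0367, 0.0339 and 0.0389 without those of day 4 and 0.024, 0.0224 and 0.0495 without those of day 5. Among them Rpl7 of the large subunit was at 657 ± 119 against 409 ± 23.7 CPM (0.66 ± 0.07).

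Immune cell genes had 11 of 14 lower and 2 higher (median -6.46, camera adjusted p = 0.000887, adjusted p = 0.193 with an estimated correlation). Ptprc, the pan-leukocyte CD45 gene, was at 0.233 ± 0.235 against 17 ± 6.48 CPM (-6.2 ± 0.55, or -7.5 without day 4 replicate 1). Fibroblast and smooth muscle genes were not called as a list (6 lower and 2 higher of 10, median -2.55, camera adjusted p = 0.12). They were called lower without crypts replicate 3 (0.00136), day 3 replicate 1, 2 or 3 (0.0444, 0.0349 and 0.0301), day 4 replicate 1, 2 or 3 (0.0361, 0.0288 and 0.0281) or day 5 replicate 1, 2 or 3 (0.0313, 0.0172 and 0.0156). The filter was applied again in each of these fits, and without day 5 replicate 1 it kept 17 genes of this list. Such calls can therefore reflect the genes added as well as the library removed. The mesenchymal filament gene Vim was lower by a ratio of 21.4 (15.3 to 30.5), while the fibronectin gene Fn1 was at 585 ± 235 against 16.8 ± 18.6 CPM (5.22 ± 0.39, or 6.47 without crypts replicate 1). Endothelial genes (1 higher and 1 lower of 5, median -0.75, camera adjusted p = 0.565) and enteric neuron and glia genes (1 higher and 2 lower of 7, median 0.01, camera adjusted p = 0.958) were not called. Pecam1, of vessel walls, was lower by a ratio of 24.9 (9.66 to 81.7), and its change of -4.95 was -5.95 without day 4 replicate 2. The median of the neuron and glia list was -0.18 with library totals. Of the red blood cell list 1 gene was tested and 0 called, and 0 mitochondrially encoded genes were in the files.

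Antimicrobial genes had 21 of 26 lower and 2 higher (median -3.95, camera adjusted p = 7.38e-06, adjusted p = 0.0727 with an estimated correlation). NF-kB and cytokine genes had 11 higher and 5 lower of 22 (median 0.6, camera adjusted p = 0.0971), with the chemokine gene Cxcl16 at 238 ± 27.6 CPM (5.42 ± 0.16) and the TNF-induced gene Tnfaip2 at 66.2 ± 12.1 CPM (7.72 ± 0.23). Interferon response genes had 34 of 40 lower and 1 higher (median -2.22, camera adjusted p = 0.000546, adjusted p = 0.538 with an estimated correlation). Crypts replicate 2 summed to 4290 CPM of these genes against 1060 and 1270 in replicates 1 and 3. Without it the median was -0.85, with 22 lower and 4 higher (camera adjusted p = 0.00931, with a range of 1.41e-05 to 0.00931 over all libraries left out in turn). Zbp1, a sensor of viral nucleic acid, was lower at -6.39 ± 0.47, or -5.42 without it. Antigen presentation genes had 13 of 19 lower and 0 higher (median -1.75, camera adjusted p = 0.000872, adjusted p = 0.307 with an estimated correlation), with the nonclassical class I gene H2-T3 lower at -7.23 ± 0.38. Their sum was 2730 CPM in crypts replicate 2 against 1410 and 1340, and without it the median was -1.31 (camera adjusted p = 0.00722, with a range of 3.1e-05 to 0.00722 over all libraries).

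In all, 3943 genes were higher and 4220 lower in monolayers than in crypts among 12863 tested, and 21 of 35 lists were called, 6 of them higher and 15 lower. With an estimated correlation 6 calls held: goblet cell, tuft cell and ion transport genes lower, and repair, YAP target and glycolysis genes higher, with adjusted p = 0.0144, 0.0173, 0.00495, 0.00835, 0.0405 and 0.0257. Adjusted over the list alone, member counts were the same except for junction (22 higher, 9 lower), colon regional identity (11 lower), cell cycle (1 higher), fibroblast (7 lower), antimicrobial (3 higher), NF-kB (6 lower), antigen presentation (14 lower), unfolded protein response (10 lower), xenobiotic metabolism (15 higher), basement membrane (25 higher) and ribosomal protein genes (12 higher, 0 lower). Other splits of the libraries into groups of 9 and 3, drawn at random, called at most 1 gene higher and 1 lower. Each of them puts crypts and monolayers in the same group, which widens the spread within it and favours low counts. The gene counts are therefore not tested by these splits. The other splits called up to 24 lists, and 23 of 100 splits, the real one among them, called at least as many lists as the real grouping. These splits divide the crypts unevenly and can keep part of the crypt difference. They therefore do not show whether the number of lists called is beyond chance. The balance of directions depends on scaling: with library totals 3094 genes were higher and 5120 lower (37.7% of calls higher, against 48.3%), and the median change of all genes was -0.207 against -0.026.

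At day 3 monolayers had less Mki67 than crypts (419 ± 80.8 CPM, -1.2 ± 0.16) and much less Krt20 and Slc26a3 (-4.94 ± 0.22 and -4.7 ± 0.2). Goblet cell genes had 30 of 33 lower (median -6.75, camera adjusted p = 2.18e-12), with Muc2 at -10.96 ± 0.64. Cldn4 was higher by 4.53 ± 0.18 and Tjp1 by 1.72 ± 0.09, and Epcam was lower at -0.76 ± 0.1 (edgeR adjusted p = 2.75e-06). Ribosomal protein genes had 27 of 39 higher and 0 lower (29 higher over the list alone, median 0.46, camera adjusted p = 0.000142, adjusted p = 0.249 with an estimated correlation). With library totals 14 of them were higher and 1 lower. Cell cycle genes had 25 of 44 lower and 1 higher (median -0.76, camera adjusted p = 0.000873, adjusted p = 0.276 with an estimated correlation), and interferon response genes 35 of 40 lower (median -3.18, camera adjusted p = 8.74e-06, adjusted p = 0.4 with an estimated correlation). Repair genes were higher for 40 of 41 (median 3.59, camera adjusted p = 4.31e-21). In total 3655 genes were higher and 3590 lower than in crypts, or 2919 and 4402 with library totals.

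Day 4 monolayers stood at 318 ± 73.3 CPM of Mki67 (-1.59 ± 0.16 against crypts), with Krt20 lower at -4.33 ± 0.22, Slc26a3 at -4.42 ± 0.2 and Muc2 at -11.49 ± 0.66. Cldn4 and Tjp1 were higher by 4.08 ± 0.18 and 1.65 ± 0.09. Lgr5 was called lower (-1.5 ± 0.43, edgeR adjusted p = 0.00624), but not without crypts replicate 2 (-0.85, 0.0959). Repair genes were higher for 40 of 41 (median 3.47, camera adjusted p = 5.7e-20) and ribosomal protein genes for 23 of 39 (median 0.37, camera adjusted p = 0.00122, adjusted p = 0.308 with an estimated correlation). Cell cycle genes had 33 of 44 lower and 1 higher (median -1.07, camera adjusted p = 1.59e-05, adjusted p = 0.206 with an estimated correlation). Interferon response genes were lower for 32 of 40 (median -2.3, camera adjusted p = 0.000381, adjusted p = 0.502 with an estimated correlation). Against crypts 3686 genes were higher and 3653 lower, or 2945 and 4416 with library totals.

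By day 5 Mki67 was at 37.6 ± 5.5 CPM against 961 ± 111 in crypts (-4.69 ± 0.19), and 39 of 44 cell cycle genes were lower (median -3.19, camera adjusted p = 9.5e-13, adjusted p = 0.0613 with an estimated correlation). Krt20 and Slc26a3 were lower than in crypts at -2.86 ± 0.2 and -3.12 ± 0.18. Absorptive colonocyte genes had 28 of 38 lower and 6 higher (median -1.25, camera adjusted p = 2.76e-05, adjusted p = 0.147 with an estimated correlation). Muc2 was lower at -10.28 ± 0.63, with 54.4 CPM in day 5 replicate 1 against 5.38 and 6.07 in replicates 2 and 3. It stood at -12.08 without replicate 1 and -9.69 without replicate 2. Repair genes were higher for 38 of 41 and lower for 2 (median 3.04, camera adjusted p = 1.04e-16). Ribosomal protein genes had 16 of 39 lower and 2 higher (median -0.23, camera adjusted p = 0.0699; 22 lower and 0 higher with library totals), and interferon response genes 21 of 40 lower and 1 higher (median -1.44, camera adjusted p = 0.0942), neither called as a list. Of all genes 3658 were higher and 3713 lower, or 2805 and 4628 with library totals. The 3 comparisons with crypts share the same crypt libraries, so their calls are not independent.

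**Figure D2:**
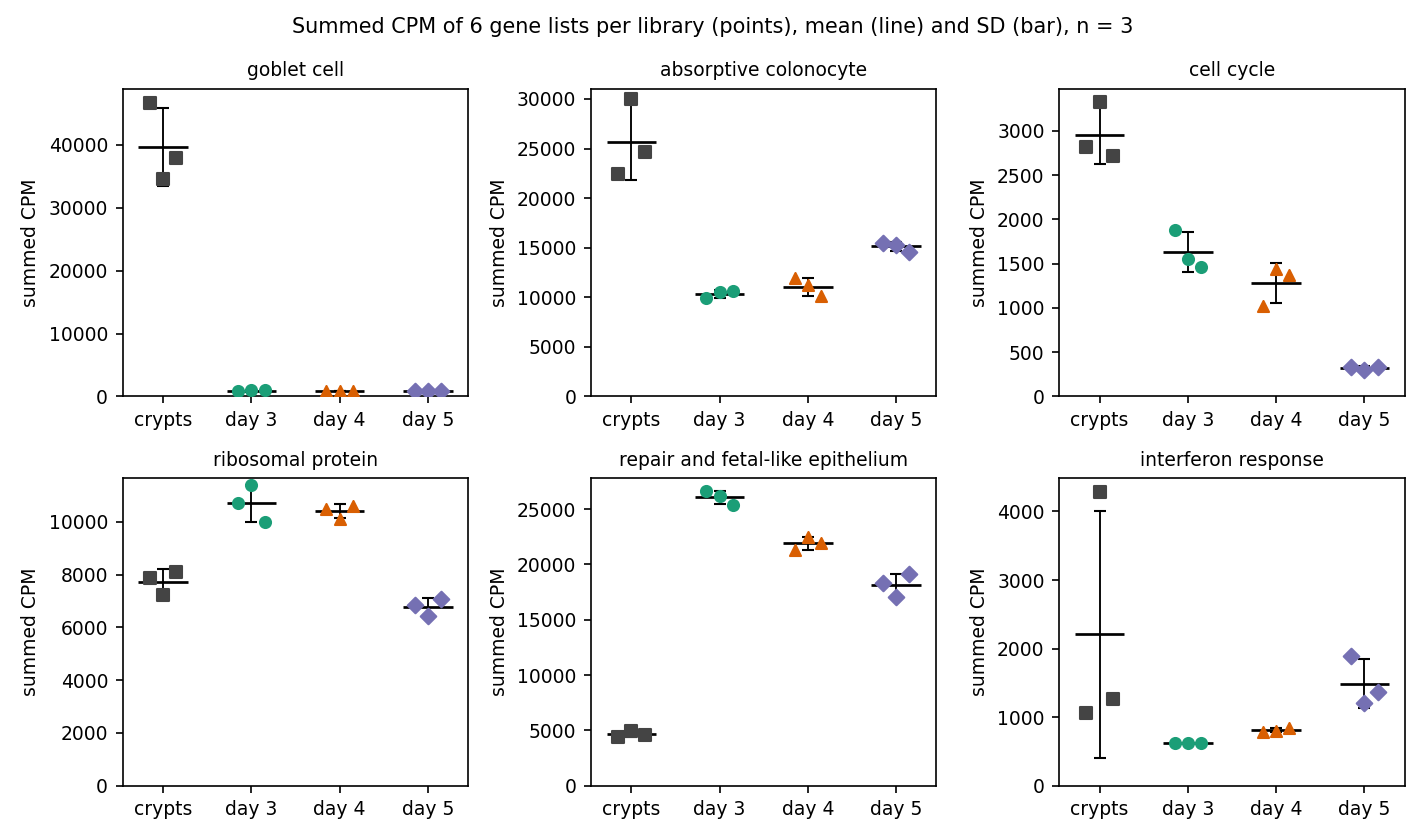
Summed CPM of 6 gene lists in each library, by group, with the mean as a line and the SD as a bar. Cell cycle genes summed to 2950 ± 324 CPM in crypts and 320 ± 22 at day 5, and goblet cell genes to 39700 ± 6250 in crypts.

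From day 3 to day 4 some genes of drug metabolism and surface cells rose, and some of protein folding fell. The sulfotransferase gene Sult1b1 went from 43.4 ± 6.39 to 130 ± 15.1 CPM (1.58 ± 0.14, edgeR adjusted p = 1.33e-05), Cyp2c55, a colonic cytochrome P450, from 60.8 ± 10.7 to 179 ± 74.5 (1.56 ± 0.23, edgeR adjusted p = 0.0013) and Lypd8, which holds flagellated bacteria off the epithelium, from 143 ± 24.6 to 370 ± 92.4 (1.37 ± 0.2, edgeR adjusted p = 0.00133). Hspa5, the chaperone BiP, fell from 981 ± 143 to 554 ± 39.8 CPM (-0.83 ± 0.1, edgeR adjusted p = 0.000205), and the vesicle transport gene Sytl2 from 112 ± 9.08 to 52.3 ± 6.1 (-1.1 ± 0.11, edgeR adjusted p = 3.56e-05). Mki67 (-0.4 ± 0.16), Krt20 (0.61 ± 0.2), Tjp1 (-0.07 ± 0.08) and Cldn4 (-0.46 ± 0.15) were not called (edgeR adjusted p = 0.242, 0.141, 0.816 and 0.12).

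By the size rule the largest increases at day 4 were Slc37a2, a sugar phosphate exchanger gene (3.47 ± 0.74), the acute phase gene Saa1 (2.87 ± 0.68), Aqp8 (2.84 ± 0.56), the carboxylesterase gene Ces1d (2.66 ± 0.57) and Cyp2d12, a cytochrome P450 gene (2.4 ± 0.61), with edgeR adjusted p = 0.0134, 0.026, 0.00903, 0.0145 and 0.04. Their levels were low, at 0.192, 0.199, 0.165, 0.56 and 0.636 CPM at day 3 and 2.12, 1.6, 1.22, 3.78 and 3.26 at day 4. They met the mean of 8 CPM only through the other groups. None of these 5 calls held without day 4 replicate 1 (0.108, 0.187, 0.106, 0.0628 and 0.366) or without day 3 replicate 2 (0.0833, 0.128, 0.0528, 0.0657 and 0.178). Without day 3 replicate 1 Slc37a2, Saa1, Ces1d and Cyp2d12 were lost (0.0608, 0.109, 0.0871 and 0.115), and without day 4 replicate 2 Slc37a2, Saa1 and Cyp2d12 (0.0672, 0.0688 and 0.0678). Without day 3 replicate 3 Aqp8 and Cyp2d12 were lost (0.0502 and 0.154) and Saa1 stood at 4.1, and Cyp2d12 was also lost without day 5 replicate 2 or 3 (0.0521 and 0.055). Trib3, a stress-induced pseudokinase gene, fell from 52.1 ± 13.4 to 17.9 ± 5.33 CPM (-1.54 ± 0.28, edgeR adjusted p = 0.00472), a call that no single library changed.

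Unfolded protein response genes fell as a list at day 4 (9 of 28 lower, 14 over the list alone, median -0.36, camera adjusted p = 1.23e-09, adjusted p = 0.145 with an estimated correlation), as did repair genes (10 of 41 lower, 15 over the list alone, median -0.26, camera adjusted p = 8.32e-07, adjusted p = 0.145 with an estimated correlation). Absorptive colonocyte genes rose (12 of 38 higher and 1 lower, 15 and 2 over the list alone, median 0.27, camera adjusted p = 8.32e-07, adjusted p = 0.267 with an estimated correlation). Xenobiotic metabolism genes (9 of 47 higher, 15 over the list alone, median 0.33, camera adjusted p = 7.72e-06, 0.145 with an estimated correlation) and glycolysis genes (5 of 33 higher, 9 over the list alone, median 0.2, camera adjusted p = 9.18e-06, 0.267 with an estimated correlation) rose as well. The glycolytic enzyme gene Gpi1 rose from 921 ± 58.7 to 1400 ± 159 CPM (0.6 ± 0.09), and Adm, a vasoactive peptide gene induced by hypoxia, from 15.1 ± 2.68 to 31.3 ± 4.52 (1.05 ± 0.19). The repair gene Anxa8 fell from 189 ± 13.3 to 107 ± 12.1 CPM (-0.82 ± 0.14). Of the other lists, cell cycle (2 of 44 lower, median -0.35, camera adjusted p = 9.18e-06, adjusted p = 0.352 with an estimated correlation), histone (3 of 18 lower and 1 higher, median -0.45, 0.000404, 0.352) and goblet cell genes (2 of 33 lower, median -0.53, 0.00394, 0.35) fell. Antigen presentation genes rose (3 of 19 higher, median 0.34, 0.00308, 0.601). Interferon response genes were called as a list at the preset correlation only (median 0.41, 0.00394, 0.794), and 0 of 40 members were called. With 1 library left out their camera adjusted p ranged from 5.74e-07 to 0.016. In every comparison of days the estimated correlation comes from all 12 libraries, among them crypts replicate 2 with its high interferon genes. Calls of 4 lists depended on 1 library. Wnt genes (median -0.22, 0.00394, 0.352 with an estimated correlation) and stem cell genes (median -0.18, 0.0153, 0.601) were lost without day 4 replicate 1 (0.0741 and 0.178). Oxidative phosphorylation genes (median 0.08, 0.0153, 0.61) were lost without it (0.146) or day 3 replicate 3 (0.314). NF-kB genes (median -0.18, 0.0385, 0.352) were lost without day 3 replicate 3 (0.168), day 4 replicate 2 (0.112) or day 4 replicate 3 (0.0926). Clock genes were called higher without crypts replicate 1 (0.0386) or 2 (0.0138), and ribosomal protein genes lower without day 3 replicate 3 (0.00619).

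Between day 3 and day 4, 205 genes rose and 151 fell, and 14 lists were called, 0 of them with an estimated correlation. The number of genes is unstable: it was 94 without day 4 replicate 1, 146 without day 3 replicate 1, 155 without day 3 replicate 2, 146 without day 3 replicate 3, 212 without day 4 replicate 2 and 739 without crypts replicate 2 and day 5 replicate 1 together. It was 490 without crypts replicate 2 and 1144 in a fit of these days alone. Only 69 of the 356 genes called in the main fit changed at least 2-fold.

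From day 4 to day 5 several proliferation genes fell and several genes of surface colonocytes rose. Mki67 fell from 318 ± 73.3 to 37.6 ± 5.5 CPM (-3.1 ± 0.18, edgeR adjusted p = 5.45e-09), and Cdc20, an activator of the anaphase-promoting complex, from 15.8 ± 2.61 to 0.614 ± 0.607 (-4.6 ± 0.42, edgeR adjusted p = 1.41e-06). Krt20 rose from 62.7 ± 19.6 to 175 ± 18.3 CPM (1.47 ± 0.2, edgeR adjusted p = 0.000116), Slc26a3 from 20 ± 6.42 to 49.6 ± 4.1 (1.3 ± 0.19, edgeR adjusted p = 0.000237) and Lypd8 from 370 ± 92.4 to 1370 ± 156 (1.88 ± 0.2, edgeR adjusted p = 8.61e-06). Slc9a3, the apical sodium-proton exchanger gene, rose from 1.71 ± 0.602 to 14.4 ± 2.35 CPM (3.03 ± 0.28, edgeR adjusted p = 1.77e-06). Ocln (0.24 ± 0.09), Cldn4 (0.35 ± 0.15) and Tjp1 (-0.05 ± 0.08) were not called (edgeR adjusted p = 0.14, 0.168 and 0.775).

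The largest increases at day 5 over day 4 also included Saa1 (4.28 ± 0.33), the transglutaminase gene Tgm3 (3.33 ± 0.28) and the peptidase gene Naaladl1 (0.737 ± 0.175 CPM at day 5, at least 6.98-fold). The carboxylesterase gene Ces2a (1.28 ± 1.68 CPM at day 5, at least 9.78-fold, edgeR adjusted p = 0.0205) was lost without day 4 replicate 1, 2 or 3 (0.0577, 0.0724 and 0.059) or day 5 replicate 1 (0.0762). The mitosis genes Ccnb1 (-5 ± 0.66), Bub1 (-4.6 ± 0.45), Nusap1 (-4.28 ± 0.38) and Iqgap3 (-4.48 ± 0.62) fell as well. These sizes varied with the day 5 library left out: Cdc20 was -5.19 and Ccnb1 and Iqgap3 were -6.97 and -6.46 without replicate 3, and the latter were -4.07 and -3.78 without replicate 2. Nusap1 was -5.24 without replicate 1 and -3.52 without replicate 2. Aqp4, a basolateral water channel gene, fell from 213 ± 43.5 to 42.2 ± 7.17 CPM (-2.34 ± 0.17), and the calcium-binding protein gene S100a6 from 1810 ± 12.5 to 1060 ± 117 (-0.78 ± 0.1).

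Cell cycle genes fell for 28 of 44 at day 5 (31 over the list alone, median -2.21, camera adjusted p = 1.48e-26, adjusted p = 0.0604 with an estimated correlation). Ribosomal protein genes fell for 27 of 39 (28 over the list alone, median -0.6, camera adjusted p = 8.2e-21, adjusted p = 0.0753 with an estimated correlation), such as Rps25 of the small subunit from 113 ± 7.39 to 59.4 ± 8.83 CPM (-0.92 ± 0.13). Absorptive colonocyte genes rose for 17 of 38 (21 over the list alone, median 0.5, camera adjusted p = 2.14e-11, adjusted p = 0.138 with an estimated correlation). Interferon response genes rose for 7 of 40 (11 over the list alone, median 0.91, camera adjusted p = 6.64e-06, adjusted p = 0.488 with an estimated correlation), or for 3 without day 5 replicate 1, with the antiviral gene Oasl2 at 3.13 ± 0.71. Repair genes fell for 11 of 41 and rose for 1 (median -0.28, 0.00056, 0.267 with an estimated correlation), such as S100a6 (-0.78 ± 0.1). The YAP target gene Ctgf fell from 711 ± 140 to 430 ± 71 CPM (-0.72 ± 0.13), but its list was not called (1 of 21 lower, camera adjusted p = 0.969). Wnt genes fell for 4 of 14 (median -0.45, 0.000233, 0.267), and Myc was lower at -0.83 ± 0.13. Histone genes fell for 7 of 18 (median -0.4, 7.98e-05, 0.299), while junction genes were called higher as a list at the preset correlation only (1 of 38 higher, 0 over the list alone, median 0.15, 0.00375, 0.488). Calls of 3 lists depended on 1 library. Antigen presentation genes (4 of 19 higher, median 0.41, 0.0106, 0.488 with an estimated correlation) were lost without day 4 replicate 2 (0.0511) and lay at the limit without day 5 replicate 3 (0.05). Stem cell genes (3 of 24 lower, median -0.2, 0.0183, 0.488) were lost without day 4 replicate 2 (0.0511), day 4 replicate 3 (0.0937) or day 5 replicate 1 (0.0976). Cholesterol synthesis genes (4 of 26 lower, median -0.19, 0.0206, 0.488) were lost without day 4 replicate 1 (0.0818) or day 5 replicate 2 (0.201). Glycolysis genes were called higher without day 4 replicate 1 (0.023) or day 5 replicate 2 (0.0388). Junction and ion transport genes both lay at the limit of 0.05 without day 5 replicate 1.

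A total of 432 genes rose and 540 fell from day 4 to day 5, and 11 lists were called, 0 of them with an estimated correlation. The number of genes was 536 without day 4 replicate 2, 553 without day 4 replicate 3 and 585 without day 5 replicate 2.

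From day 3 to day 5 several proliferation genes fell and several colonocyte genes rose. Mki67 fell from 419 ± 80.8 to 37.6 ± 5.5 CPM (-3.5 ± 0.18, edgeR adjusted p = 6.24e-10) and Hmmr, of the mitotic spindle, from 42.4 ± 1.86 to 1.67 ± 1.47 (-4.52 ± 0.38). Krt20 rose from 41.3 ± 6.2 to 175 ± 18.3 CPM (2.08 ± 0.2, edgeR adjusted p = 8.8e-07), Slc26a3 from 16.5 ± 4.03 to 49.6 ± 4.1 (1.58 ± 0.19, edgeR adjusted p = 8.55e-06), Lypd8 from 143 ± 24.6 to 1370 ± 156 (3.25 ± 0.21, edgeR adjusted p = 8.82e-09) and Epcam from 1010 ± 21.5 to 2000 ± 132 (0.98 ± 0.1, edgeR adjusted p = 1.2e-06). Lgr5 fell from 7.17 ± 0.482 to 1.95 ± 0.945 CPM (-1.95 ± 0.48, edgeR adjusted p = 0.00681). The junction genes Tjp1 (-0.12 ± 0.08), Ocln (0.23 ± 0.09), Cldn4 (-0.11 ± 0.15) and Cdh1 (0.13 ± 0.08) were not called (edgeR adjusted p = 0.343, 0.0865, 0.664 and 0.272). Muc2 was not called either (0.68 ± 0.55, edgeR adjusted p = 0.418), although it was called lower (-1.13) without day 5 replicate 1 (0.00314).

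By the size rule Saa1 rose most from day 3 to day 5 (32.1 ± 7.31 against 0.199 ± 0.232 CPM, 7.16 ± 0.44, or 8.39 without day 3 replicate 3). Slc37a2 (5.51 ± 0.6), Cyp2d12 (4.85 ± 0.58) and Slc9a3 (4.38 ± 0.32) rose as well. Car4 and the carboxylesterase gene Ces1g rose from no count (each at least 3.4-fold, edgeR adjusted p = 0.0273 and 0.0338). Both were lost without day 3 replicate 1 (0.0594 and 0.0724), replicate 2 (0.0717 and 0.0891) or replicate 3 (0.0648 and 0.0793) and without day 5 replicate 1 (0.128 and 0.0762), and Ces1g also without day 5 replicate 3 (0.0699). Ccnb1 (-5.51 ± 0.65), Iqgap3 (-5.21 ± 0.59), Bub1 (-4.83 ± 0.44) and Cdc20 (-4.63 ± 0.41) fell. Without day 5 replicate 3 Ccnb1, Iqgap3 and Cdc20 were -7.49, -7.19 and -5.22, and without replicate 2 Ccnb1 and Iqgap3 were -4.58 and -4.51. Sval1, a seminal vesicle antigen-like gene, fell to no count at day 5 (at least 7.46-fold).

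Cell cycle genes fell for 36 of 44 and rose for 1 between day 3 and day 5 (37 and 1 over the list alone, median -2.57, camera adjusted p = 7.01e-23, adjusted p = 0.072 with an estimated correlation). Ribosomal protein genes fell for 29 of 39 (33 over the list alone, median -0.66, camera adjusted p = 1.09e-16, adjusted p = 0.072 with an estimated correlation), with Rps2 of the small subunit going from 328 ± 18.6 to 132 ± 22.9 CPM (-1.31 ± 0.15). Repair genes fell for 23 of 41 and rose for 1 (26 and 1 over the list alone, median -0.56, camera adjusted p = 9.43e-08, adjusted p = 0.072 with an estimated correlation), among them the growth factor gene Ereg, from 163 ± 8.03 to 57.6 ± 2.32 CPM (-1.49 ± 0.19). Absorptive colonocyte genes rose for 25 of 38 and fell for 2 (28 and 3 over the list alone, median 1.02, camera adjusted p = 4.17e-13, adjusted p = 0.072 with an estimated correlation). Wnt genes fell for 8 of 14 (median -0.87, camera adjusted p = 5.25e-05, adjusted p = 0.186 with an estimated correlation), among them Myc from 253 ± 25.8 to 92.9 ± 15.3 CPM (-1.44 ± 0.13). Stem cell genes fell for 9 of 24 and rose for 2 (median -0.43, 0.00133, 0.389 with an estimated correlation), including the hyaluronan receptor gene Cd44 (-1.51 ± 0.17). Histone genes fell for 10 of 18 and rose for 1 (median -0.93, 3.4e-06, 0.186).

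Interferon response genes rose for 18 of 40 and fell for 1 between day 3 and day 5 (28 and 1 over the list alone, median 1.59, camera adjusted p = 7.51e-08, adjusted p = 0.478 with an estimated correlation). Ifit3, which blocks viral RNA translation, went from 2.51 ± 1.12 to 26.8 ± 16 CPM (3.41 ± 0.78, edgeR adjusted p = 0.00401). Without day 5 replicate 1 the median was 1.31, with 15 higher (camera adjusted p = 1.28e-06, with a range of 3.04e-15 to 1.31e-06 over all libraries). Antigen presentation genes rose for 6 of 19 (8 over the list alone, median 0.7, camera adjusted p = 0.000327, adjusted p = 0.42 with an estimated correlation), with the class I gene H2-Q2 going from 21.2 ± 2.97 to 118 ± 1.63 CPM (2.46 ± 0.24). Glycolysis genes (13 of 33 higher and 1 lower, median 0.24, 5.25e-05, 0.205 with an estimated correlation), xenobiotic metabolism genes (18 of 47 higher and 4 lower, median 0.69, 0.000315, 0.186) and clock genes (5 of 18 higher, median 0.52, 0.016, 0.302) rose. Sult1b1 went from 43.4 ± 6.39 to 287 ± 54.4 CPM (2.72 ± 0.14) and the clock repressor gene Cry2 was higher by 0.79 ± 0.15. Calls of 3 lists depended on 1 library. Unfolded protein response genes (12 of 28 lower and 1 higher, median -0.15, 0.0185, 0.42), with the asparagine synthetase gene Asns falling from 194 ± 25.9 to 51.9 ± 6.16 CPM (-1.9 ± 0.12), were lost without day 5 replicate 3 (0.0768). Colon regional identity genes (5 of 18 higher and 1 lower, median 0.47, 0.0276, 0.389) were lost without day 5 replicate 2 (0.065) or 3 (0.0768). Junction genes (4 of 38 higher, 1 over the list alone, median 0.11, 0.0276, 0.478) were lost without day 3 replicate 2 (0.0587) or day 5 replicate 1 (0.131).

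**Figure D3:**
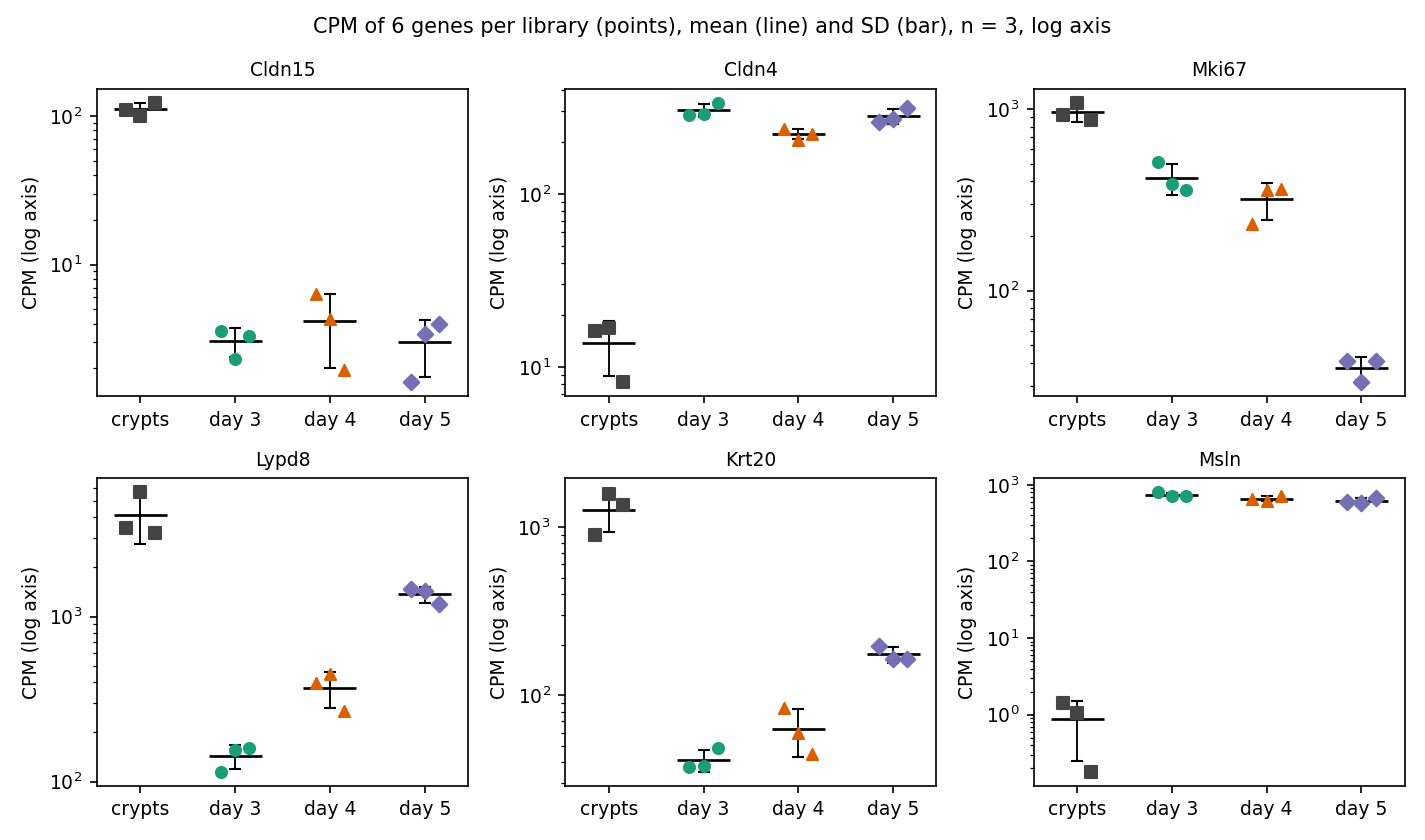
CPM on a log axis of Cldn15, Cldn4, Mki67, Lypd8, Krt20 and Msln in each library, by group, with mean and SD. Mki67 stood at 961 ± 111 CPM in crypts and 37.6 ± 5.5 at day 5.

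Over the whole interval 1273 genes rose and 1347 fell, 877 of them at least 2-fold, and 15 lists were called, 0 of them with an estimated correlation. Goblet cell genes (8 of 33 lower and 1 higher, camera adjusted p = 0.114) and ion transport genes (13 of 32 higher and 7 lower, camera adjusted p = 0.241) were among the lists not called. Goblet cell genes were called lower without day 3 replicate 1 (0.0229) or day 5 replicate 1 (0.0128), and oxidative phosphorylation genes higher without day 3 replicate 2 (0.0494). Reads without a unique alignment were 17.8 ± 0.808% at day 3 and 15.3 ± 1.01% at day 5, and ribosomal protein genes have many near-identical copies, so their counts are less certain.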

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

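The test of the size of the interferon change without 1 crypt library was chosen only after that result was seen, as were the counts of genes on opposite sides under other scalings. All other tests named here were set before their results were seen.

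A total of 75 genes lay on opposite sides of the crypts at day 3 and day 5, with calls at both days and between them, where both days are compared with the same crypt libraries. Of these, 48 were higher than crypts at day 3 and lower at day 5, 27 were lower and then higher, and 12 were members of the tested ribosomal list, which leaves out ribosomal genes such as Rpl41. Chosen after the values were seen, the phosphodiesterase gene Gdpd2 went from -1.91 ± 0.51 to 1.97 ± 0.45 relative to crypts, the cytochrome P450 gene Cyp2d26 from -1.56 ± 0.26 to 1.42 ± 0.24, the focal adhesion gene Tln2 from 1.56 ± 0.13 to -0.47 ± 0.13, the proline synthesis gene Aldh18a1 from 0.94 ± 0.16 to -0.91 ± 0.17 and Rps2 from 0.85 ± 0.14 to -0.46 ± 0.15. With library totals 71 genes changed sides, 7 of them members of that list, and 32 were shared with the 75. With DESeq2 size factors 77 did, 11 of them members, and 65 were shared. Which genes change sides therefore depends partly on scaling.

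Whether any grouping of the libraries would give such counts was tested by splitting the same libraries in other ways, drawn at random for monolayers and crypts and in full for pairs of groups. For monolayers and crypts, 3691 genes were higher and 3717 lower in the fit of these groups alone, and 1 of 100 splits, the real one, gave as many, with 1 and 1 in the highest other split. Every other split puts crypts and monolayers in the same group, which widens the spread within it and favours low counts. This comparison therefore cannot tell whether the gene counts arise from an arbitrary grouping. For lists, 23 of 100 splits called at least the 21 lists of the real grouping and the highest other called 24. Such splits divide the crypts unevenly and can keep part of the crypt difference, so the count of lists stays undecided. For each pair of groups of 3 only 10 splits exist, which is too few to test. The real counts were 7145, 6845 and 6079 genes for day 3, day 4 and day 5 against crypts, 1144 for day 4 against day 3, 1069 for day 5 against day 4 and 2996 for day 5 against day 3, and the highest other count was 0 each time. For lists the real counts were 15, 12 and 16 in the same order of days, against at most 9, 9 and 10 in other splits.

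The lower interferon genes in monolayers could come from 1 crypt library with an active response. Without crypts replicate 2 the list kept its call (camera adjusted p = 0.00931, with a range of 1.41e-05 to 0.00931 over all libraries left out in turn, but 0.538 with all libraries and an estimated correlation), while its median shrank to -0.85. Without scaling factors the median was -2.39, so scaling does not produce it. At the preset correlation the direction held without crypts replicate 2, while most of the size may belong to that library. Whether its response came from the animal, the isolation or retained immune cells would need crypts of further mice, with the same genes measured by qPCR.

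The fall of cell cycle and ribosomal protein genes from day 3 to day 5 could reflect the shallower day 5 libraries or day 5 replicate 1 alone. Without that library the camera adjusted p was 1.54e-27 for cell cycle and 5.85e-17 for ribosomal protein genes, with ranges of 1.54e-27 to 1.48e-20 and 1.43e-18 to 1.27e-14 over all libraries left out in turn, but 0.072 for both lists with all libraries and an estimated correlation. With all libraries thinned to one total the medians were -2.6 and -0.71, so neither depth nor that library accounts for the fall at the preset correlation. From day 3 to day 5 Malat1 went from 5.81 ± 0.165 to 11 ± 1.51% of gene counts and the ribosomal RNA gene Rn45s from 8.91 ± 0.0808 to 5.17 ± 1.36%, and whether such a shift in RNA composition contributes was not tested. Cells may also leave the cycle as the cultures age, which EdU labelling on each day would test.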

How the results depend on the processing

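Requiring a 2-fold change left 1872 genes higher and 2430 lower in monolayers than crypts, 4104, 4153 and 4219 changed at day 3, day 4 and day 5 against crypts, and 69, 327 and 877 for day 4 against day 3, day 5 against day 4 and day 5 against day 3. Testing against 1.5-fold with glmTreat left 2199, 2557, 4326, 4348, 4389, 7, 158 and 611 in that order. A stricter size rule lowers these counts by construction. For day 4 against day 3 the 356 genes became 636 with no filter, 609 with DESeq2, 612 with limma-voom, 1144 in the fit of these groups alone and 739 without crypts replicate 2 and day 5 replicate 1 together, an alternative chosen after seeing the data. The main fit shares its estimate of spread with the crypts and day 5, while the fit of these groups alone does not. How much this accounts for the differences was not tested. With each library left out in turn the counts were 3722 to 4129, 3921 to 4594, 6539 to 7908, 6827 to 7991, 6891 to 7518, 94 to 490 (146, 155 and 146 without a day 3 library, 212 without day 4 replicate 2), 536 to 1207 (553 and 585 also under 1/1.5 of the count) and 1811 to 2871. Lists called were 21 to 24 for monolayers, 11 to 15, 9 to 11 and 13 to 16 for the pairs of days, 6, 0, 0 and 0 with an estimated correlation and 32, 5, 7 and 16 with fry. The replicate block gave 3896, 4100, 7060, 7192, 7228, 314, 900 and 2463 genes and 22, 14, 11 and 15 lists. Of 11866 values of named genes, 11046 kept their direction and side of the threshold whatever their size, 676 lost a call, 77 gained one, 65 changed sign uncalled or had no adjusted p, and 2 changed direction with a call: Cdh1 to -0.16 with library totals (edgeR adjusted p = 0.0274) and Muc2 to -1.13 for day 5 against day 3 without day 5 replicate 1 (1.26 without replicate 2). For called genes 165 of 6108 sizes with 1 library left out and 115 of 4056 in other settings shifted at least 1.5-fold. Of 840 list medians under the other scalings and filters, DESeq2 and the replicate block, 793 stayed within 1 SD between replicates and 47 moved beyond it, 21 with library totals, 22 with no filter and 4 with the block, and this count has no library left out. All alternatives were run.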

Other observations

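The comparisons with basal keratinocyte markers described here and the limit of 0.1 were chosen only after the squamous genes were seen. The comparison of the day 3 to day 5 change with crypts was set before its result was seen, but the lists shown for it were chosen after.

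Monolayers expressed genes of squamous epithelium that crypts lack almost entirely. The summed level of 9 such genes was 1220 ± 130 CPM at day 3, 734 ± 82.3 at day 4 and 449 ± 70.1 at day 5, against 11.4 ± 9.31 in crypts. Krt4 and Sprr1a carry most of this sum and its decline. Krt4 fell over the days, from 278 ± 35 to 147 ± 37.2 and 14.6 ± 6.11 CPM, and so did the cornified envelope gene Sprr1a, from 816 ± 104 to 451 ± 32 and 292 ± 48.5. Serpinb11 went the other way, with 42.8 ± 1.86, 72.9 ± 13.8 and 90.2 ± 24.5 CPM, and Lor, Ly6d and Alox12b stood at similar levels at day 3 and day 5 (13.5 and 12.3, 8.96 and 8.77, 15.7 and 17.9 CPM). Krt13 and Sprr1a alone of the 9 had counts in crypts, 2 and 277. Sprr1a is also a member of the repair list.

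These squamous genes could come from keratinocytes carried into the cultures. Basal keratinocytes would bring Krt5, Krt14 and Trp63, yet 6 basal markers summed to 14.7 ± 0.652 CPM at day 3, a share of 0.0121 of the squamous sum. The share depends on the most abundant genes: it was 0.0368 without Sprr1a and 0.121 without Sprr1a and Krt4, which is above the limit of 0.1. Krt5 stood at 0.275 CPM and Trp63 at 0.097, while Krt14, also a member of the repair list, made up most of the sum and fell as Krt4 and Sprr1a did, from 12.5 ± 0.246 at day 3 to 2.47 ± 1.05 at day 5, against 0.438 ± 0.264 in crypts. The share therefore does not settle whether keratinocytes were present, and the source stays open. Another reading, that colonic cells switch on these genes as in wound repair, might be tested by staining monolayers for Krt4 together with Cdx2.

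A move of the monolayers towards the crypts with time was tested across 12863 genes, by comparing day 5 minus day 3 with crypts minus day 4, which share no library. The correlation was 0.018, so a general move towards crypts is not seen. Of 2620 genes changed from day 3 to day 5, 1865 also differed between day 4 and crypts, 1075 of them moving towards crypts and 790 away. Among the lists with at least 20 such genes, absorptive colonocyte (23 towards, 3 away), repair (23 and 1), ribosomal protein (22 and 0) and xenobiotic metabolism genes (17 and 4) moved mostly towards crypts, and cell cycle genes away (1 and 29). Some ribosomal protein genes went past the crypts, with 12 higher than crypts at day 3 and lower at day 5. Differences between lists were not tested. Of the lists with fewer such genes, interferon response (17 and 0) and fatty acid oxidation genes (10 and 1), for example, moved towards crypts. The interferon level of crypts, a sum of 2210 ± 1810 CPM, rests largely on crypts replicate 2. As a list, fatty acid oxidation genes were not called from day 3 to day 5 (median -0.02, camera adjusted p = 0.442). Glycolysis (2 and 12), histone (0 and 9) and goblet cell genes (1 and 8) moved away. A possible explanation, not tested here, is that the cells mature as surface colonocytes and stop dividing while crypts keep a dividing compartment. Ion transport genes (10 and 8) do not follow it. Surface cells and crypt base cells sorted from the same colon would be the comparison to make.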
